A study of Mus musculus with 18 samples.

How the data were processed

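Liver total RNA of female mice aged 6 to 8 weeks was profiled on 18 Affymetrix GeneAtlas MG-430 PM arrays, a format whose probe sets hold perfect-match probes only. Per the labels' protocols, RNA was extracted with Trizol and amplified and labelled by the Affymetrix 3′-IVT procedure, which copies transcripts from their 3′ end. Groups were taken from the sample titles: wild type (n = 5) and mice carrying an NPC1L1 transgene in the liver (n = 5), both on C57BL/6, and mice given an antisense oligonucleotide (ASO) against ACAT2 (n = 4) or a non-targeting control ASO (n = 4), both on C57BL/6N. The labels number the samples of a group without stating separate animals, so the p-values measure the spread between these samples, which may be partly technical.

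The deposited log2 values are probe set summaries made by the authors with RMA, per the submitters' processing notes. The software version and the probe set definition are not given in the sources used here. The log2 scale was taken from the range of the values. The median per array lay between 4.61 and 4.65 in the transgenic model and between 4.38 and 4.40 in the ASO model, so RMA may have been run on each model separately, and levels are compared only within a model. No pair of arrays held identical values (0 pairs). The number of arrays per group limits the precision of each value.

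Each array held 45141 probe sets, and 104 control probe sets were left out. The platform annotation gave 1 gene symbol for 28898 probe sets, several for 551 and none for 15588. Of the 28898, 28689 matched the mouse gene table by Entrez number (assembly GRCm38.p6), and 0 symbols changed. A gene was represented by its probe set with the highest mean over all arrays, which left 17097 genes, 7180 of them with more than 1 probe set. No filter on low values was applied. The transcript that the ASO targets was not analysed here, so its knockdown was not checked.

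Differences were tested with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes, in a single fit with a mean per group over all 18 arrays. The contrasts were transgenic minus wild type, ACAT2 ASO minus control ASO, and the difference between these 2 effects. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard errors given with log2 changes are limma's moderated values, and group values are given as mean ± SD. Overlaps of called genes were set against the number that independent lists of the same sizes give. The models share no arrays.

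The 30 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 536 list members 460 were measured, between 4 and 26 per list. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists of a comparison, and again with a correlation estimated for each list. Member counts are given over all genes tested and adjusted over the list alone.

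The naming rule took the genes Npc1l1 and Nnt, up to 10 called rises and 10 called falls per comparison with the largest change among genes whose groups did not overlap, genes called in both comparisons, up to 5 genes per direction for the difference of the effects, and up to 4 members per list with the smallest p. Predicted genes without a name were passed over. The text gives 2 such members for each of 10 lists, and those lists were picked after the values were seen. Other probe sets are given for called genes by their sign, and for other genes named in the text where one had the opposite sign or under 0.5 of the change.

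The procedure was tested on simulated data with the real group means and spreads and 200 genes changed. For the transgenic comparison it recovered 59 of 67 genes changed by 0.5 on the log2 scale, 63 of 67 changed by 1 and 66 of 66 changed by 2, with 11 calls among 16897 unchanged genes. For the ASO comparison the numbers were 55 of 67, 61 of 67 and 66 of 66, with 16 such calls. Calls with no gene changed numbered 0 in each. A list of 20 genes shifted by 0.3 was recovered in each comparison, and 4.5% and 5% of unshifted lists had p under 0.05. The simulated noise was independent between genes, so the list rates do not cover lists whose members vary together. The estimated correlation was 0.41 for the list of sterol biosynthesis genes and 0.22 for that of lipid droplet genes.

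The alternatives of the tests covered a filter removing the 40% of genes with the lowest mean, centring each array on its median, quantile normalization within each model, the mean of a gene's probe sets, every probe set by itself, fits on each comparison's own arrays, a trended and robust variance, array weights, the replicate number as a block, a fold minimum of 1.5, an adjusted p under 0.01, a rank test for lists, and leaving out each array in turn. Alternatives added after seeing the data are named as such. Figures were drawn with matplotlib 3.10.9.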

Results

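Hepatic transcript levels were compared in 2 mouse models in which transintestinal cholesterol excretion, a route of cholesterol loss that bypasses bile, was stimulated. Stimulation was chronic in mice with an NPC1L1 transgene in the liver (n = 5 samples, against 5 wild-type samples). It was acute after an antisense oligonucleotide (ASO) against ACAT2 (n = 4 samples, against 4 with a non-targeting ASO). The stated purpose was to find regulators of reverse cholesterol transport, the return of cholesterol from tissues for excretion. RMA log2 values were available for 17097 genes. The first principal component held 33.8% of the variance in the transgenic model and 43.1% in the ASO model. The difference between 3′ and 5′ control probe sets of Actb, a sign of RNA integrity, averaged 1.02 ± 0.17 in transgenic and 0.91 ± 0.08 in wild-type liver (SD, n = 5, exact permutation p = 0.254, adjusted over 4 comparisons p = 0.825). It averaged 1.05 ± 0.11 after ACAT2 ASO and 1.05 ± 0.05 after control ASO (SD, n = 4, exact permutation p = 0.971, adjusted p = 0.971). The same difference for Gapdh gave exact permutation p = 0.413 and p = 0.857 (adjusted p = 0.825 and 0.971).

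Npc1l1, the intestinal cholesterol transporter gene that the transgene is named for, lay near the lower end of the scale on all arrays. The wild-type arrays 1 to 5 read 3.73, 3.64, 3.66, 3.93 and 4.16, and the transgenic arrays read 3.73, 3.75, 3.68, 3.61 and 3.61 (limma adjusted p = 0.604), a difference of -0.15, or -0.06 without wild type 5. The arrays of the ACAT2 ASO group read 4.21, 4.24, 4.31 and 4.36, and the control ASO arrays read 4.27, 4.26, 3.90 and 4.15 (limma adjusted p = 0.619), a difference of 0.14, or 0.06 without control ASO 3. The labels do not state the species of the transgene, so this mouse probe set neither checks nor contradicts the group labels. Nnt, a mitochondrial transhydrogenase gene that carries a deletion in the C57BL/6J substrain, read 10.30, 10.20, 10.30, 10.41 and 10.37 in wild-type and 10.18, 10.10, 10.37, 10.19 and 10.13 in transgenic liver (limma adjusted p = 0.656). It read 10.46, 10.72, 10.85 and 10.76 after ACAT2 ASO and 10.64, 10.59, 10.65 and 10.25 after control ASO (limma adjusted p = 0.476). The ASO difference was 0.16, or 0.07 without control ASO 4. The other Nnt probe set differed by -0.03 in transgenic liver and by -0.02 after ACAT2 ASO.

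In transgenic liver the largest named rise was that of Dio1, the type 1 deiodinase that activates thyroid hormone, from 8.53 ± 0.36 to 9.87 ± 0.39 (SD, n = 5), a log2 change of 1.34 ± 0.21 (SE, limma adjusted p = 0.00726). Ifi27, an interferon-inducible gene, rose by 0.87 ± 0.13 (limma adjusted p = 0.00462) and Acyp2, an acylphosphatase gene, by 0.74 ± 0.10 (limma adjusted p = 0.00179). Genes for 4 subunits of the proteasome, the complex that degrades ubiquitinated proteins, also rose: Psmd14 by 0.44 ± 0.06, Psmd1 by 0.42 ± 0.05, Psmb3 by 0.39 ± 0.05 and Psmc4 by 0.39 ± 0.07 (limma adjusted p between 0.0015 and 0.0174). Unc13b, a vesicle priming gene, rose by 0.59 ± 0.09, Rexo2, an oligoribonuclease gene, by 0.38 ± 0.07, and Cltb, a clathrin light chain gene, by 0.37 ± 0.07. The largest fall was that of the C-type lectin gene Clec2h, from 6.03 ± 0.40 to 4.67 ± 0.43 (SD, n = 5), a log2 change of -1.36 ± 0.19 (SE, limma adjusted p = 0.0034). Its other probe sets differed by -2.86 and -2.14. Cib3, a calcium-binding protein gene, changed by -1.08 ± 0.16, the glutathione peroxidase family gene Gpx6 by -0.77 ± 0.07 and the serine protease gene Prss8 by -0.60 ± 0.10 (limma adjusted p = 0.00462, 0.000179 and 0.0139). Duxbl1, Irf2bpl, Hs3st3b1, Arntl2 and Mgat4b fell by 0.45, 0.41, 0.32, 0.28 and 0.24 on the log2 scale.

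**Figure D1:**
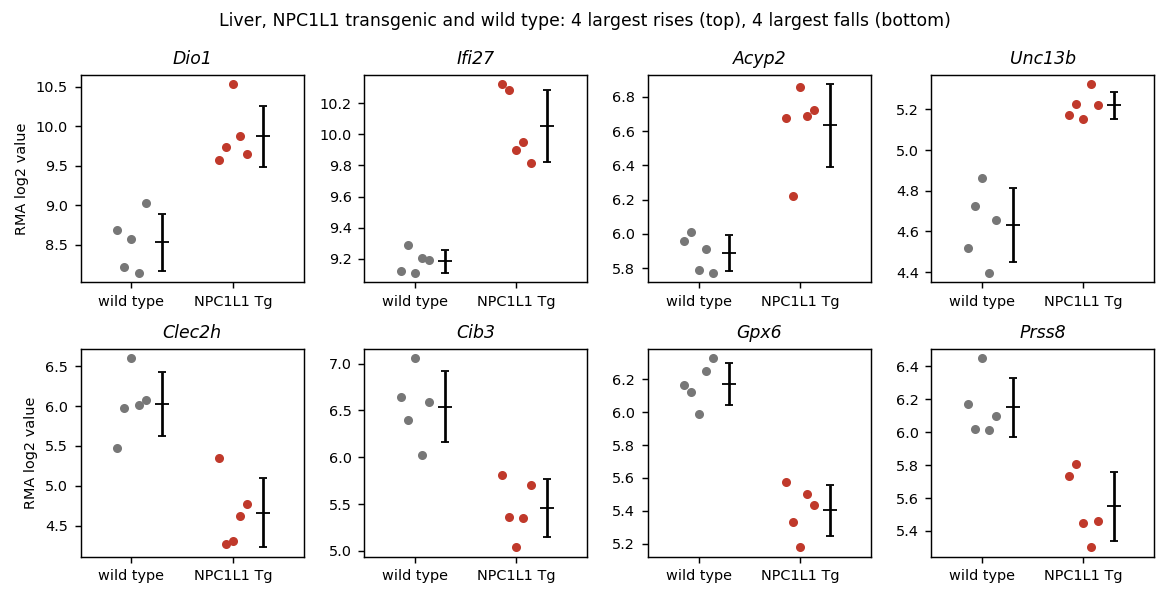
RMA log2 values of the 4 called genes with the largest named rises (top) and falls (bottom) in NPC1L1 transgenic (Tg) against wild-type liver, with 1 point per array and the mean ± SD beside each group of 5. Only genes whose groups do not overlap could be picked, and the log2 change is 1.34 for Dio1 and -1.36 for Clec2h.

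Of 17097 genes, limma called 39 in transgenic liver, 29 higher and 10 lower, against 1859 at an unadjusted p under 0.05. The change reached 1.5-fold for 8 genes and 2-fold for 3. The 19 named genes had 15 other probe sets, 11 with the same sign. All 7 of those with a mean above 4.74, the level under which the lowest 40% of genes lay, had the same sign, and the 4 of opposite sign, all below it, differed by -0.03 for Unc13b, 0.01 for Duxbl1, 0.10 for Hs3st3b1 and 0.08 for Arntl2. Sizes differed: the other probe sets of Cltb differed by 0.15 and 0.22 and that of Irf2bpl by -0.13. Those of Ifi27, Psmb3 and Psmc4 differed by 0.92, 0.25 and 0.34. The count was 20 without wild type 3, 24 without wild type 4 and 24 without transgenic 4, 13 in a fit of these 10 arrays alone and 78 with every probe set tested. The call of Psmc4 ended without wild type 3, wild type 4 or transgenic 1 (highest limma adjusted p = 0.0577, without the last), and that of Rexo2 without any of these or transgenic 4 (highest 0.0649, without transgenic 4). The calls of Cltb and Irf2bpl (0.0988 each), Mgat4b (0.0988) and Arntl2 (0.127) also had their highest p without transgenic 4, and ended without each single array except wild type 5, transgenic 2 and 3 for Cltb, wild type 4, transgenic 2 and 3 for Irf2bpl, wild type 5 and transgenic 3 for Mgat4b, and wild type 5 and transgenic 1 for Arntl2.

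The list of sterol biosynthesis genes and targets of SREBP2, the transcription factor that raises cholesterol synthesis, was lower in transgenic liver by camera (adjusted p = 0.000107). The call was lost with an estimated correlation (adjusted p = 0.993 with an estimated correlation). Of its 20 measured members 18 lay below 0, with a median change of -0.20, and the mean over members was 7.38 ± 0.13 in transgenic and 7.66 ± 0.28 in wild-type liver (SD, n = 5). Limma called 0 members over all genes tested and 2 lower when adjusted over the list alone. Sqle, squalene epoxidase, differed by -0.88 ± 0.21 (SE, limma adjusted p = 0.088) and Lss, lanosterol synthase, by -0.68 ± 0.18 (limma adjusted p = 0.138). The wild-type 1 array had the highest list mean, 8.10, and without it the median change was -0.10 (camera adjusted p = 0.0198), against -0.33 without wild type 5.

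Lipid droplet and steatosis genes were higher as a list (camera adjusted p = 0.028, and adjusted p = 0.993 with an estimated correlation). Of 15 measured members 13 lay above 0, with a median change of 0.23 and list means of 7.50 ± 0.10 against 7.24 ± 0.17 (SD, n = 5). Limma called 0 members over all genes and 1 higher when adjusted over the list alone. G0s2, an inhibitor of triglyceride lipolysis, differed by 1.02 ± 0.26 (SE, limma adjusted p = 0.123) and Fitm1, a lipid droplet assembly gene, by 0.81 ± 0.29 (limma adjusted p = 0.298). The median change was 0.11 without wild type 2 and 0.09 without wild type 3, with camera adjusted p = 0.0647 and 0.15. The list's adjusted p was 0.0546 without transgenic 1 and 0.12 without transgenic 3.

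The other 28 lists were not called in transgenic liver, with camera adjusted p between 0.056 and 0.988. Bile acid synthesis and transport genes had a median change of 0.08 with 16 of 24 members above 0 (camera adjusted p = 0.056) and 1 member higher when adjusted over the list alone. This list was called without wild type 1 (camera adjusted p = 0.038), wild type 4 (0.0391), wild type 5 (0.017) or transgenic 2 (0.0385). With an estimated correlation its adjusted p was 0.366, and the lowest without a single array 0.177. Baat, which conjugates bile acids, differed by 0.28 ± 0.06 (limma adjusted p = 0.0813), and Cyp7b1, of the alternative bile acid pathway, by 0.54 ± 0.18 (limma adjusted p = 0.251), while other probe sets of the 2 genes differed by 0.08 (Baat) and by 0.54 and 0.02 (Cyp7b1). LXR targets had a median change of 0.05, and lipoprotein and cholesterol ester genes one of 0.00059, each with 1 member lower when adjusted over the list alone. Pltp, the phospholipid transfer protein gene in both lists, differed by -0.58 ± 0.15 (limma adjusted p = 0.112). Mylip, an LXR-induced ligase gene for the LDL receptor, differed by 0.17 and Apoe by 0.07. The 4 measured flavin monooxygenases had a median change of -0.03, with Fmo1 at -0.10 and Fmo2 at -0.15 (limma adjusted p = 0.672 and 0.907). Fmo1 differed by -0.06 without transgenic 1 or transgenic 4. Without single arrays Fmo2 lay between -0.27 and 0.045, the latter without transgenic 1, and its other probe sets differed by -0.20, -0.23 and 0.02.

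Among the remaining metabolic lists the median change in transgenic liver was 0.05 for fatty acid and triglyceride synthesis, 0.09 for fatty acid oxidation and PPARA targets, 0.12 for xenobiotic metabolism, 0.10 for female-predominant and -0.01 for male-predominant genes, 0.04 for NRF2 targets and -0.00014 for gluconeogenesis and insulin response. Cyp2b9 and Hao2, of the female-predominant list, differed by 0.45 ± 0.23 and 1.20 ± 0.68 (limma adjusted p = 0.498 and 0.555), and the median of that list was -0.15 without wild type 5 and -0.20 without transgenic 3. The median was -0.02 for the unfolded protein response, 0.0045 for circadian clock genes, 0.0062 for the cell cycle, 0.01 for the lysosome and -0.14 for immediate early genes. For markers of other cell types it was 0.07 for macrophages and Kupffer cells, 0.08 for lymphocytes, -0.03 for neutrophils, -0.0028 for sinusoidal endothelium, -0.02 for stellate cells and matrix, -0.03 for cholangiocytes, -0.01 for pancreatic acinar cells, 0.11 for adipocytes and 0.00061 for erythroid cells. Hepatocyte markers had a median of -0.0039, interferon-stimulated genes one of 0.03 (0.29 without wild type 2 and -0.10 without wild type 5) and acute phase genes one of 0.01. Adjusted over the list alone, 2 pancreatic acinar genes were higher and 1 adipocyte gene was lower. The signs of median, mean and camera's direction differed for 10 of the 30 lists, namely lipoprotein, male-predominant, interferon-stimulated, sinusoidal endothelial, pancreatic acinar, circadian, unfolded protein response, cell cycle, gluconeogenesis and lysosome. Over all lists limma called 0 of 460 members, with 32 at an unadjusted p under 0.05.

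Some of these lists were called in transgenic liver without a single array. Fatty acid oxidation and PPARA targets were higher without wild type 4, wild type 5 or transgenic 5 (camera adjusted p = 0.0135, 0.0119 and 0.0458), and fatty acid and triglyceride synthesis genes without wild type 1 (camera adjusted p = 0.0198). Without wild type 1 immediate early genes were lower (camera adjusted p = 0.038). Xenobiotic metabolism genes were higher without transgenic 1 (camera adjusted p = 0.0133), and interferon-stimulated genes and lymphocyte markers without wild type 2 (camera adjusted p = 0.0136 and 0.021). With an estimated correlation as well, a combination chosen after seeing the data, 0 lists were called in any of these 10 fits. Of their results 10 had an unadjusted p under 0.05, and outside the bile acid list the lowest adjusted p was 0.805. Single arrays also moved medians over 1.5 times. Without wild type 2 the median was 0.26 for macrophage and 0.16 for lymphocyte markers, 0.12 for NRF2 targets, 0.23 for female-predominant and -0.06 for immediate early genes. Without wild type 1 it was 0.17 for fatty acid and triglyceride synthesis and -0.22 for immediate early genes, and without wild type 5 it was 0.16 for fatty acid oxidation. Without transgenic 1 it was 0.29 for female-predominant genes and 0.12 for macrophage markers, without transgenic 2 0.15 for macrophage markers and -0.09 for immediate early genes, and without transgenic 3 0.12 for fatty acid and triglyceride synthesis and -0.23 for immediate early genes. Of the other uncalled lists 17 had a median that changed sign without some single array, and the largest absolute median of these was 0.0941.

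After ACAT2 ASO the largest named fall was that of Exoc4, a subunit of the exocyst that tethers secretory vesicles, from 7.42 ± 0.25 to 5.58 ± 0.43 (SD, n = 4), a log2 change of -1.84 ± 0.17 (SE, limma adjusted p = 1.25e-05). Tpd52l1, a gene of the tumor protein D52 family, changed by -1.82 ± 0.13 (limma adjusted p = 1.42e-06), and Sugct, which acts in glutarate metabolism, by -1.40 ± 0.20 (limma adjusted p = 0.00243). The endosomal SNARE gene Stx8 changed by -1.07 ± 0.09, the mitochondrial carrier gene Sfxn5 by -1.03 ± 0.10 and the nuclease gene Snd1 by -0.96 ± 0.08 (limma adjusted p = 4.26e-06, 1.53e-05 and 6.32e-06). The cytochrome P450 gene Cyp2j6 changed by -1.02 ± 0.17, the glutathione transferase gene Gsta4 by -1.00 ± 0.21, the F-box gene Fbxl17 by -0.96 ± 0.14 and Atrnl1 by -0.90 ± 0.11. The largest named rise was that of the adhesion receptor gene Adgrv1, by 1.00 ± 0.16 from 5.73 ± 0.26 to 6.72 ± 0.16 (SD, n = 4, limma adjusted p = 0.00809). Tcf24 rose by 0.94 ± 0.20, the periplakin gene Ppl by 0.80 ± 0.16 and Ccnd1, the cyclin of entry into the cell cycle, by 0.69 ± 0.12 (limma adjusted p = 0.0416, 0.031 and 0.0159). The corepressor gene Tle1 rose by 0.61 ± 0.10 and the prolyl hydroxylase gene Egln3 by 0.61 ± 0.13. Man2a2, Ccdc162, the growth factor gene Tgfa and the hydroxysteroid dehydrogenase gene Akr1c14 rose by 0.53, 0.49, 0.41 and 0.39.

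**Figure D2:**
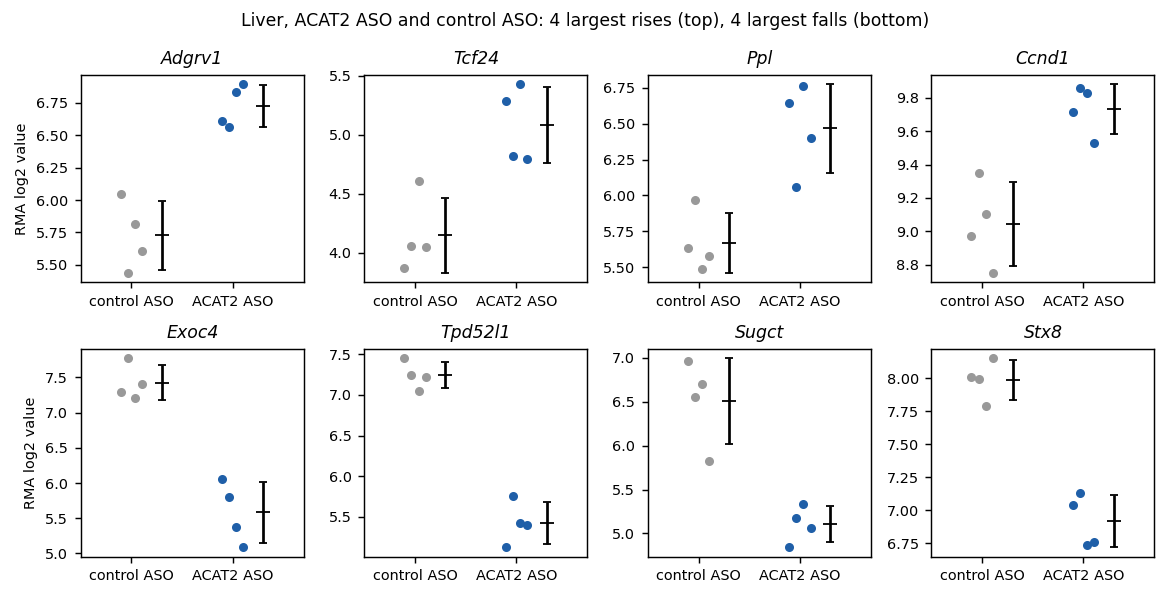
RMA log2 values of the 4 called genes with the largest named rises (top) and falls (bottom) after ACAT2 ASO against control ASO, with 1 point per array and the mean ± SD beside each group of 4. Only genes whose groups do not overlap could be picked, and Exoc4 averages 7.42 after control ASO and 5.58 after ACAT2 ASO.

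Limma called 102 of 17097 genes after ACAT2 ASO, 31 higher and 71 lower, against 2276 at an unadjusted p under 0.05. The change reached 1.5-fold for 29 genes and 2-fold for 6. The 20 named genes had 15 other probe sets, 14 with the same sign, among them 10 of 10 with a mean above that level of 4.74, and that of Adgrv1, with a mean of 3.07, differed by -0.03. Sizes differed between probe sets: the others of Exoc4 differed by -1.77, -1.09, -0.14 and -0.07, those of Stx8 by -0.86 and -0.14, and that of Fbxl17 by -0.10. That of Atrnl1 differed by -0.16, that of Egln3 by 0.19 and those of Tgfa by 0.09 and 0.03. Nearer in size were that of Cyp2j6 (-0.97) and those of Ccnd1 (0.50 and 0.54). The same sign thus does not mean a change of the same size. The count was 203 without ACAT2 ASO 2, 55, 42 and 49 without ACAT2 ASO 1, 3 and 4, and 50 and 47 without control ASO 1 and 2. It was 465 with array weights, 219 with every probe set, 17 in a fit of these 8 arrays alone, and 46 without the arrays that stand apart (wild type 2, ACAT2 ASO 1 and control ASO 4, chosen after seeing the data). The call of Ccnd1 ended without ACAT2 ASO 3 or control ASO 1 (highest limma adjusted p = 0.0618), that of Tgfa without ACAT2 ASO 1 or 3 (0.0613), that of Ccdc162 without ACAT2 ASO 3, ACAT2 ASO 4 or control ASO 1 (0.0658), and that of Gsta4 without ACAT2 ASO 1, ACAT2 ASO 3 or control ASO 1, 2 or 3 (0.113). The calls of Ppl (0.113), Egln3 (0.125), Tcf24 (0.139), Man2a2 (0.124) and Akr1c14 (0.137) ended without each single array except ACAT2 ASO 2 and control ASO 2 for Ppl, ACAT2 ASO 2 and control ASO 3 for Egln3 and Tcf24, control ASO 1 for Man2a2 and control ASO 2 for Akr1c14. The highest p came without ACAT2 ASO 3 for Ccnd1, Tgfa, Ppl and Akr1c14, without ACAT2 ASO 4 for Man2a2, and without control ASO 1 for the other genes named.

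Camera called 0 of 30 lists after ACAT2 ASO, with 6 at an unadjusted p under 0.05 and adjusted p between 0.0775 and 0.995, and with an estimated correlation 0 lists had p under 0.05. Macrophage and Kupffer cell markers came closest, with 20 of 22 above 0, a median change of 0.33 and list means of 7.95 ± 0.66 against 7.61 ± 0.60 (SD, n = 4, camera adjusted p = 0.0775). Cd163 and Vsig4, receptors of resident macrophages, differed by 0.96 ± 0.39 and 0.55 ± 0.24 (SE, limma adjusted p = 0.292 and 0.313), and by 0.64 and 0.29 without ACAT2 ASO 1. The highest list means were 8.84 on ACAT2 ASO 1 and 8.50 on control ASO 4. This list was called without ACAT2 ASO 3 (camera adjusted p = 1.87e-05), without ACAT2 ASO 4 (0.0214) and without control ASO 4 (1.19e-06), and without ACAT2 ASO 1 its median change was 0.03. Without control ASO 4 the sterol (0.0286), acute phase (0.0131) and cholangiocyte (0.0131) lists were called as well. With an estimated correlation too, 0 lists were called without any single array, with 1 result at an unadjusted p under 0.05 and a lowest adjusted p of 0.837. All 13 measured female-predominant genes lay below 0 with a median change of -0.47 (camera adjusted p = 0.219), and Cyp2b13, a P450 gene of female liver, differed by -1.17 ± 0.60 (limma adjusted p = 0.415). ACAT2 ASO 1 had the lowest list mean, 6.82 against 7.80 to 8.07 on the others of its group, and read 7.71 for Cyp2b13, against at least 10.1. Without it the median of the list was -0.27 (camera adjusted p = 0.777) and Cyp2b13 differed by -0.56.

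Sterol biosynthesis genes and SREBP2 targets had a median change of -0.23 after ACAT2 ASO, with 17 of 20 below 0 (camera adjusted p = 0.219), and Sc5d and Ggps1, of the sterol and isoprenoid pathways, differed by -0.39 and 0.26. That median was -0.10 without ACAT2 ASO 1 or control ASO 1 and Sc5d differed by -0.22 without the latter, and other probe sets differed by 0.06 and -0.09 (Sc5d) and by -0.01 and 0.28 (Ggps1). Lipid droplet genes had a median of -0.14, with 12 of 15 below 0 (camera adjusted p = 0.219), and one of -0.05 without control ASO 1. G0s2 and Abhd5, of that list, differed by -0.66 and -0.18, and G0s2 by -0.40 without ACAT2 ASO 1. Bile acid genes had a median of 0.0098, with Cyp2c70, which makes muricholic acids, at 0.27 and Baat at -0.20 (limma adjusted p = 0.0928 and 0.204). LXR targets had a median of -0.0083, with Apoc2 at -0.31 and Abcg8, a sterol exporter gene, at 0.45 (limma adjusted p = 0.176 and 0.311). Lipoprotein and cholesterol ester genes had one of -0.03, with Apom, an HDL apolipoprotein gene, at -0.32 and the cholesterol ester hydrolase gene Nceh1 at -0.25 (limma adjusted p = 0.102 and 0.131), where the other probe sets of Nceh1 differed by -0.05 and -0.13. The flavin monooxygenases had a median of -0.12, with Fmo2 at -0.56 and Fmo4 at -0.17 (limma adjusted p = 0.446 and 0.57). They differed by -0.33 and -0.10 without ACAT2 ASO 1, and Fmo4 by -0.09 without control ASO 1. Other probe sets of Fmo2 differed by -0.71, -0.91 and -0.04. Adjusted over the list alone, 2 lipoprotein genes, 1 fatty acid oxidation gene and 1 lysosome gene were lower and 1 bile acid gene was higher. Limma called 0 of the 460 members over all genes, with 34 at an unadjusted p under 0.05.

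In the remaining lists the median change after ACAT2 ASO was -0.05 for fatty acid and triglyceride synthesis, 0.01 for fatty acid oxidation and PPARA targets, -0.01 for xenobiotic metabolism, 0.05 for male-predominant genes, -0.03 for NRF2 targets, -0.09 for gluconeogenesis and insulin response and 0.05 for the unfolded protein response. It was -0.0011 for circadian clock genes, 0.01 for the cell cycle, -0.04 for the lysosome and -0.10 for immediate early genes (0.02 without control ASO 1). For cell type markers it was 0.01 for lymphocytes, 0.07 for neutrophils, 0.02 for sinusoidal endothelium, -0.0034 for stellate cells and matrix, -0.17 for cholangiocytes, 0.02 for pancreatic acinar cells, -0.08 for adipocytes, -0.0067 for erythroid cells and 0.03 for hepatocytes. Acute phase genes had a median of 0.02, with Fga at 0.11 and Apcs at -0.46, and interferon-stimulated genes one of -0.16, with Oas2 at 0.23 and Ifit1 at -0.51 (limma adjusted p = 0.362 and 0.684). Both medians, Apcs and Ifit1 depended on control ASO 4: without it the medians were 0.11 and, with the sign reversed, 0.13 (camera adjusted p = 0.0131 and 0.0553), and Apcs and Ifit1 differed by -0.11 and 0.0013. The signs of median, mean and camera's direction differed for 7 lists, namely LXR targets, fatty acid oxidation, bile acid, male-predominant, stellate cell, erythroid and gluconeogenesis. Single arrays moved further medians over 1.5 times. Without ACAT2 ASO 1 the median was -0.36 for interferon-stimulated genes, -0.13 for NRF2 targets, -0.11 for cholangiocytes, -0.09 for lipid droplet genes, -0.08 for flavin monooxygenases and -0.04 for immediate early genes. Without ACAT2 ASO 2 it was -0.38 for sterol genes, -0.13 for fatty acid and triglyceride synthesis and 0.14 for neutrophils. Without ACAT2 ASO 3 it was 0.55 for macrophages, 0.13 for neutrophils, -0.11 for interferon-stimulated and -0.16 for immediate early genes, and without ACAT2 ASO 4 -0.15 for sterol genes and -0.14 for adipocytes. The interferon-stimulated median was -0.28, -0.25 and -0.33 without control ASO 1, 2 and 3. Without control ASO 1 the median was -0.07 for flavin monooxygenases, without control ASO 2 -0.08 for cholangiocytes and -0.18 for immediate early genes, and without control ASO 3 -0.10 for NRF2 targets. Without control ASO 4 it was 0.65 for macrophages, 0.13 for lymphocytes, 0.12 for the unfolded protein response, 0.11 for the cell cycle, -0.12 for fatty acid and triglyceride synthesis and -0.07 for immediate early genes. The other 14 medians also moved over 1.5 times without some single array, 11 of them with a change of sign, and the largest absolute median of these was 0.1004.

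Interferon-stimulated, acute phase and macrophage genes were high together on a few arrays of both models. The mean of the interferon-stimulated genes was 8.69 on wild type 2, against at most 7.60 on the other wild-type arrays, and 7.83 on control ASO 4, against 6.21 to 6.29 on the other control arrays. The macrophage list averaged 9.33 on wild type 2, 8.50 on control ASO 4 and 8.84 on ACAT2 ASO 1. In transgenic liver Itgax and Trem2, of the macrophage list, differed by 0.35 and -0.10, Mx2 and Stat2, of the interferon-stimulated list, by -0.14 and -0.18, and Itih4 and Saa4, of the acute phase list, by 0.12 and 0.24 (limma adjusted p between 0.495 and 0.677). Another probe set of Trem2 differed by 0.32. Itgax differed by 0.21 without transgenic 5 and Trem2 by -0.06 without transgenic 3. Mx2 and Stat2 differed by -0.09 and -0.05 without wild type 2, Mx2 by -0.09 without transgenic 4 and Stat2 by -0.12 without transgenic 2. Without wild type 2, control ASO 4 and ACAT2 ASO 1, left out together after seeing the data, the transgenic comparison had 6 called lists (2 with all arrays). The interferon-stimulated, acute phase and macrophage lists were among the 6, but the arrays had been picked by their values in these lists, so that these calls are no test of them.

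**Figure D3:**
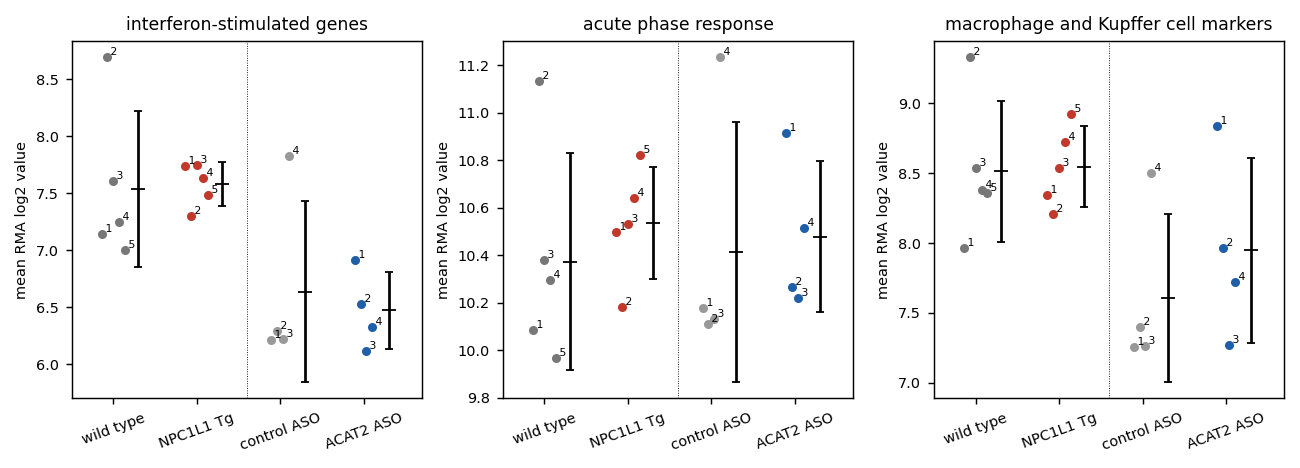
Mean RMA log2 value per array of the interferon-stimulated, acute phase and macrophage lists in the 4 groups, with array numbers beside the points and the mean ± SD of each group of 5 or 4, and a dotted line between the models, whose levels are not compared. Wild type 2, at 8.69, and control ASO 4, at 7.83, stand above the rest of their groups in the interferon-stimulated list.

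To ask which genes responded alike in both models, the calls were joined. Psmd2, a proteasome subunit gene, was the only gene called in the same direction, rising by 0.31 ± 0.04 in transgenic liver and by 0.28 ± 0.05 after ACAT2 ASO (SE, limma adjusted p = 0.00392 and 0.0119). Its other probe set, with a mean of 4.39, differed by 0.08 and -0.02. Independent lists of these sizes would share 0.0526 genes that rise and 0.0415 that fall. Hdgfl2, of the hepatoma-derived growth factor family, rose by 0.25 ± 0.05 in transgenic liver and changed by -0.27 ± 0.05 after ACAT2 ASO (limma adjusted p = 0.0341 and 0.031), where 0.12 such genes would be shared by chance. Of the 39 genes called in transgenic liver 14 had the same sign after ACAT2 ASO, and of the 102 called after ACAT2 ASO 39 had the same sign in transgenic liver. At an unadjusted p under 0.05 in both, 43 genes were higher in both (61.7 for independent lists), 30 lower in both (58.9) and 266 opposite (127). Genes vary together, so the distance of these counts from those of independent lists is no test. Across all genes, which are not independent replicates, the changes correlated with r = -0.083 and rho = -0.128, and r ran from -0.114 to -0.047 without single arrays. Without wild type 4 or wild type 5, 45 and 96 genes had the same direction (73 with all arrays). Both calls of Hdgfl2 ended without each single array except wild type 2 and transgenic 3 in one and ACAT2 ASO 2 and control ASO 1 in the other (highest limma adjusted p = 0.112 without transgenic 4 and 0.105 without ACAT2 ASO 4). Hdgfl2 was also not called in both under the filter on low values, with the trended robust variance, in fits of each comparison's own arrays or with the block. The count of 1 gene called in the same direction became 0 in fits of each comparison's own arrays and with the mean of a gene's probe sets, where Psmd2 after ACAT2 ASO had a change of 0.13 (adjusted p = 0.0993).

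**Figure D4:**
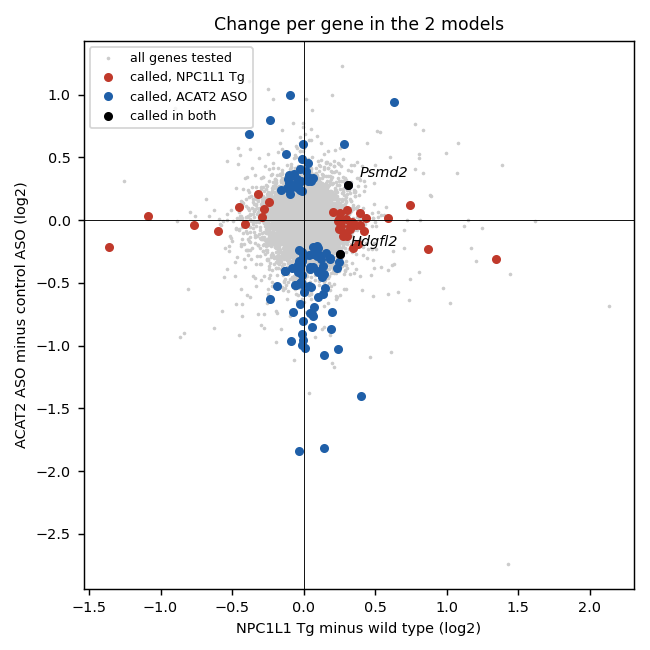
Log2 change of each of 17097 genes in NPC1L1 transgenic against wild-type liver (x axis) and after ACAT2 ASO against control ASO (y axis), with called genes as larger points. Psmd2 (0.31 and 0.28) and Hdgfl2 (0.25 and -0.27) are the genes called in both.

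The difference between the effects was tested in the same fit. Tpd52l1, Sugct, Exoc4 and Dio1 had the largest named differences toward the transgenic model, 1.96 ± 0.17, 1.81 ± 0.27, 1.80 ± 0.22 and 1.66 ± 0.31 (SE, limma adjusted p = 3.88e-05, 0.00389, 0.000818 and 0.017). Rdh16, a retinol dehydrogenase family gene that was called in neither comparison, differed by 1.55 ± 0.32 (limma adjusted p = 0.0317). Toward the ASO model stood Cib3, Adgrv1, Ccnd1, Ppl and Mcc, with differences of -1.12, -1.09, -1.07, -1.03 and -0.94 (limma adjusted p between 0.0054 and 0.0371). Cib3 read 3.55 to 3.86 on the arrays of the ASO model, near the lower end of the scale, where a fall could not show, so its difference does not show an effect specific to a model. The 4 other probe sets of Mcc differed by -0.10 to -0.02 in transgenic liver and by -0.04 to 0.09 after ACAT2 ASO, against -0.37 and 0.57 for the one used. Ccnd1 differed by -0.38 in transgenic liver, where it was not called (limma adjusted p = 0.194), and rose by 0.69 after ACAT2 ASO. Limma called 183 genes in all, 131 with a higher and 52 with a lower effect in transgenic liver. The count was 118, 86, 111, 109 and 96 without wild type 1, wild type 3, transgenic 1, transgenic 3 and transgenic 4, 76, 69 and 74 without ACAT2 ASO 1, 3 and 4, and 83, 87 and 116 without control ASO 1, 2 and 3. It was 369 with array weights, 350 with every probe set and 58 without the 3 arrays that stand apart. The call of Adgrv1 ended without ACAT2 ASO 3, ACAT2 ASO 4 or control ASO 2 (highest limma adjusted p = 0.0636), and that of Rdh16 without wild type 3, transgenic 3, transgenic 4, ACAT2 ASO 3, control ASO 1 or control ASO 2 (0.0598). That of Cib3 (0.0767) ended without wild type 1, transgenic 3, transgenic 4 or any array of the ASO model but ACAT2 ASO 2, and that of Ppl (0.0715) without wild type 1 or 3, transgenic 1 or 3, or any array of the ASO model but ACAT2 ASO 2 and control ASO 2. That of Mcc (0.083) ended without wild type 1 or 3, transgenic 1, 4 or 5, ACAT2 ASO 1, 3 or 4, or control ASO 1 or 4. The highest p came without ACAT2 ASO 4 for Adgrv1 and Cib3 and without ACAT2 ASO 3 for the others.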

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

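All tests in this part were chosen before the results were seen, but the named genes they cover were picked by their values in these data. Within each group, the array farthest from the rest was set against Dixon's critical value for 334 groups of values, and 26 exceeded it (7.78%), where chance gives about 1 in 20 groups. These were 12 values of single genes and 14 list means or array measures.

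Control ASO 4 stood apart in list means of immune genes. It read 11.2 for the acute phase response (others 10.1 to 10.2), 7.83 for interferon-stimulated genes (others 6.21 to 6.29), 8.50 for macrophage markers (others 7.26 to 7.40), 5.13 for lymphocyte markers, 5.11 for neutrophil markers and 5.05 for the cell cycle. Its first principal component score was -26.6, with the other control arrays between 10.3 and 11.8. Its Apcs value was 11.2, its Ifit1 value 7.14 and its Nnt value 10.25 (others 10.59 to 10.65). Control ASO 1 stood apart for lipid droplet genes (7.73, others 7.29 to 7.31), with G0s2 at 11.2, Apoc2 at 11.8 and Rdh16 at 9.28. Control ASO 2 had a stellate cell and matrix mean of 6.75. ACAT2 ASO 1 had a sinusoidal endothelial mean of 7.51 and a Cyp2b13 value of 7.71 (others 10.1 to 10.2).

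In the transgenic model, wild type 2 was low for lipoprotein and cholesterol ester genes (9.97, others 10.09 to 10.14) and for gluconeogenesis and insulin response genes (8.63, others 9.28 to 9.42). Transgenic 5 had a stellate cell and matrix mean of 7.10 (others 6.74 to 6.82). Transgenic 1 was low for Rdh16 (8.56) and Baat (9.50), transgenic 2 was low for Acyp2 (6.22) and high for Lss (5.37), transgenic 4 was high for Psmd14 (9.93), and transgenic 3 had a median of 4.61 over all probe sets.

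For 31 named genes the transgenic effect differed from the ASO effect by limma's test of the difference. Most were named for a call in 1 comparison or for this difference itself, so their number is no test. Differences toward the transgenic model were 1.96 for Tpd52l1, 1.81 for Sugct, 1.80 for Exoc4, 1.66 for Dio1, 1.55 for Rdh16, 1.27 for Sfxn5, 1.21 for Stx8, 1.10 for Ifi27, 1.03 for Cyp2j6, 0.95 for Snd1, 0.90 for Atrnl1, 0.87 for Fbxl17, 0.63 for Acyp2, 0.57 for Rexo2, 0.52 for Hdgfl2, 0.51 for Psmd1, 0.48 for Baat, 0.43 for Psmb3 and 0.42 for Psmd14. Differences toward the ASO model were -1.12 for Cib3, -1.09 for Adgrv1, -1.07 for Ccnd1, -1.03 for Ppl, -0.94 for Mcc, -0.72 for Gpx6, -0.65 for Man2a2, -0.56 for Duxbl1, -0.53 for Hs3st3b1, -0.44 for Tgfa, -0.39 for Mgat4b and -0.37 for Arntl2. In the ASO model Cib3 (3.55 to 3.86) and Gpx6 (4.52 to 4.80) had low values on each array, which left no room for a fall like that in transgenic liver in the first and little in the second, so their differences do not show effects specific to a model. Over all genes 183 were called.

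Among 15588 probe sets without a gene name, which the report used only in its counts over every probe set, limma called 20 in transgenic liver (12 higher, 8 lower) and 68 after ACAT2 ASO (42 higher, 26 lower), in a fit of every probe set. That is 0.128% and 0.436% of them, against 0.197% and 0.513% of the annotated probe sets.

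Other splits of the arrays were fitted in the same way. In the transgenic model the real split called 39 genes and the highest of the others 5, so that 1 of 100 splits (of 126 possible) gave as many and chance can be excluded at that level. In the ASO model the real split called 102 genes and the highest other 22. Chance can be excluded there only at the level of 1 of 35, the lowest share that these splits can give. For the difference of the effects the numbers were 183 and 25, in splits that regrouped both models at once. At the level of 1 of 100 this excludes only chance in both models together. A real effect in 1 model is enough to exceed 25: with only the transgenic arrays regrouped, up to 68 genes were called for the difference. These splits thus cannot decide whether the 2 effects differ. For genes called in both in the same direction the numbers were 1 and 0. Only 2 of the 99 other splits called any gene in each comparison, so that they had almost none to share and the count says nothing on chance. For the negative correlation of the effects across genes chance cannot be excluded: 71 of 100 splits gave a value as far from 0 as -0.083, and the farthest was 0.579. None of these splits can tell the treatment from other differences between the groups, such as litter or housing.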

How the results depend on the processing

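Leaving out wild type 2, ACAT2 ASO 1 and control ASO 4 together, and an estimated correlation with each array left out, were chosen after the results were seen, and the other alternatives were planned. The cause of a change was not tested unless the setting itself gives it. The counts of called genes, 39 in transgenic liver, 102 after ACAT2 ASO and 183 for the difference, stayed within 1.5 times under the filter on low values, median centring, quantile normalization, the mean of a gene's probe sets and the trended robust variance. Centring moved the share of higher calls from 30.4% to 21.2% after ACAT2 ASO and from 71.6% to 81.4% for the difference. Testing every probe set gave 78 (49 higher, 29 lower), 219 (91 and 128) and 350 (198 and 152) probe sets. Fits of each comparison's own arrays, which have fewer degrees of freedom, gave 13 (12 higher, 1 lower) and 17 (1 and 16), where all arrays in 1 fit gave 29 and 10 in transgenic liver and 31 and 71 after ACAT2 ASO. Array weights gave 465 after ACAT2 ASO and 369 for the difference. A fold minimum of 1.5 left 8, 29 and 42, and an adjusted p under 0.01 left 17, 26 and 28, as a stricter limit must. The 8 were 4 higher and 4 lower, and the 26 were 3 and 23. Without the 3 arrays 46 genes (6 higher, 40 lower) were called after ACAT2 ASO, 36 of them among the 102, and 58 for the difference. The single gene called in both in the same direction became 0 with the mean of probe sets, own arrays, the fold minimum, the stricter p and the block. The single gene called in opposite directions became 0 with the filter on low values, own arrays, the trended robust variance, the fold minimum, the stricter p and the block.

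With the replicate number as a block, 2 (0 higher, 2 lower), 18 (2 and 16) and 12 (10 and 2) genes were called. The numbers do not pair the arrays: same-numbered deviations correlated at 0.17, -0.48, 0.05, -0.03 and -0.22 in the transgenic model and at -0.48, 0.11, 0.47 and -0.31 in the ASO model, and only control ASO 3 correlated best with its own number. With the block 3 lists were called in transgenic liver, the added one that of bile acid genes.

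Leaving out 1 array at a time gave 20 to 58 genes in transgenic liver, 42 to 203 after ACAT2 ASO, 69 to 262 for the difference and 1 throughout for both. Of 53 calls of named genes 31 were kept without each single array, and 0 changed sign. The number of called lists ran from 1 to 5 in transgenic liver (2 in the report) and from 0 to 4 after ACAT2 ASO (0 in the report). In transgenic liver it was 6 without the 3 arrays, 5 in a fit of own arrays and 0 with an estimated correlation, with or without each array. After ACAT2 ASO it was 2 without the 3 arrays, which were picked by their immune lists, macrophage markers included, 1 with a rank test and 2 with the mean of probe sets. The sterol list had an adjusted p of 0.993 with an estimated correlation and 6.03e-07 to 0.0198 without single arrays. The lipid droplet list had 0.993, 0.0533 without the 3 arrays, and 0.0119 to 0.15 without single arrays. Among genes that were not called, 3 changed sign: Trem2 in transgenic liver (0.11 with the mean of probe sets), Fmo2 in transgenic liver (-0.27 to 0.045 without single arrays, above 0 without transgenic 1) and Ifit1 after ACAT2 ASO (-0.70 to 0.0013, above 0 without control ASO 4). Signal over background limits low genes such as Npc1l1, where a change would be compressed.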

Other observations

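The proteasome and gene-length groups described here, and the tests of them, were chosen after the results were seen. The test of other probe sets for the long genes was recorded as set beforehand, but it acts on a group found in these same calls. Proteasome subunits were higher together in NPC1L1 transgenic liver. All 30 measured constitutive subunits of the 20S core and 19S cap lay above 0, with a median change of 0.25 (0.07 to 0.44), and limma called 11 over all genes tested and 27 adjusted over the list alone. Psmb5, a catalytic subunit, rose by 0.32 ± 0.04 (SE, limma adjusted p = 0.000659), Psmc3 by 0.30 ± 0.05 and Psmd4, a ubiquitin receptor, by 0.31 ± 0.05 (limma adjusted p = 0.00731 and 0.0125). The mean over subunits was 9.76 ± 0.05 in wild-type and 10.01 ± 0.04 in transgenic liver (SD, n = 5), with no overlap between the groups. After ACAT2 ASO the median was 0.02 and limma called 1, Psmd2. Counting every measured gene whose symbol begins with Psma, Psmb, Psmc or Psmd, 34 of 37 lay above 0 in transgenic liver and 11 were called. The number of called subunits was 7 without wild type 3 or without wild type 4 and in a fit of own arrays, 6 at an adjusted p under 0.01, and 0 with a fold minimum of 1.5. With the replicate number as a block 0 genes were called higher in transgenic liver, and so 0 subunits.

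A general shift of abundant genes by the normalization would move other genes of that level too. Random lists matched on level had a median of 0.02 (highest of 10000, 0.12), which argues against such a shift of this size. None of these lists reached the median of the subunits (share 0.0001, the smallest the draws can give). The subunits were picked from these calls, so that share is no test of chance. Wild type 2, which stood apart in immune genes, had the highest subunit mean of the wild-type arrays, 9.81, so that it could not make the rise. Without it the median was 0.24 ± 0.03 (SE). An interferon response stays open: Psmb8, Psmb9 and Psmb10 of the immunoproteasome averaged 0.028 ± 0.256 (SE over samples), too wide to exclude a rise like that of the others. Among splits of the arrays 1 of 100, the real one, gave a median as far from 0 (0.25, highest other -0.18), but the list was picked from the calls of that split, which makes this no test of chance. A coordinated response to the chronic transgene may be a candidate explanation, and litter or housing differences between the groups another, both untested.

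Some of the falls after ACAT2 ASO lay in long genes, while most did not: the median span was 24.4 kb for the called falls and 20.2 kb for all genes. Of 71 called falls 10 lay in genes spanning over 200 kb, where random draws matched on level held 2 (median). The share of draws with as many was 0.0005, but gene span was noticed in these same falls, which makes this no test of chance. The 10 were Exoc4, Sugct, Stx8, Fbxl17, Snd1, Atrnl1, Babam2, Ptprg, Sil1 and Dtnb, with a median change of -0.93. Babam2 changed by -0.85, Ptprg by -0.80 and Sil1 by -0.74 (limma adjusted p = 1.34e-05, 0.000571 and 0.000571). Of 31 called rises 2 were that long (share 0.36), as was 1 of the 39 genes called in transgenic liver (share 0.77). With limits of 100 and 400 kb, 17 and 6 falls were longer, against 8 and 1 in matched draws. Without single arrays between 9 and 17 called falls were longer than 200 kb, the highest without ACAT2 ASO 2. Spans were taken from the gene table (assembly GRCm38.p6, while the build behind the array is not given in the sources used here) and were known for 16936 genes.

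A fall of long genes in general is opposed by all 240 genes that long at or above the lowest level of the 10, called ones included. Their median change was -0.013 ± 0.022 (SE over samples, with an SD of 0.30 over genes). Gene span includes introns, so this cannot decide on RNA quality, which acts on the transcript. The difference between 3′ and 5′ control probe sets of Actb averaged 1.05 after ACAT2 ASO and 1.05 after control ASO. These probe sets do not cover the 10 genes, so an effect of RNA quality on some of them stays open. Without ACAT2 ASO 1 and control ASO 4, 10 of 38 called falls were that long (9 of them also called with all arrays), against 1 in matched draws (share 0.0001, the smallest the draws can give), so those arrays do not make the pattern. Faulty single probe sets stay open for these genes as a set. All 12 other probe sets were lower, but their median of -0.22 ± 0.15 did not clear the bound of -0.1 set beforehand by its standard error. For Exoc4 and Stx8 other probe sets argue against a single faulty one. They changed by -1.77 and -1.09 (Exoc4) and by -0.86 (Stx8, limma adjusted p of at most 7.56e-06 for each). The rest differed by -0.14 and -0.07 (Exoc4) and -0.14 (Stx8), and those of Fbxl17 and Atrnl1 by -0.10 and -0.16. Cleavage of long precursor transcripts at partial matches to the oligonucleotide could be a candidate explanation, and a response to loss of the target another. Neither was tested, since the oligonucleotide sequence was not used here.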
